A study of Gallus gallus and Homo sapiens with 8 samples.

How the data were processed

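Small RNA was profiled in 8 libraries in 4 groups of 2: shRPA3 in mir30, shRPA3 in ultramiR (both in ERC chicken cells), shRenilla in mir30 and shRenilla in ultramiR (both in HEK293 human cells). Groups and replicate letters came from the sample titles. Per the labels' protocols, cells were infected at copy number 1 and selected with G418 at 1 mg/ml to an infection rate of 95%, RNA shorter than 200 bases was isolated with the mirVana kit, and libraries were made with an Illumina small RNA kit. The series text gives the infection rate as over 90%.

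The authors deposited 2 tables, one per cell line, with log2-like variance-stabilized values per microRNA row and library. Per the submitters' processing notes, Bowtie and DESeq were used with the builds galGal4 and hg19, and their versions and settings are not given in the sources used here. Which build served which table is given only by the species of the cell line. The tables were normalized separately, and 0 deposited value columns were left unused. The chicken rows are named by hairpin locus and the human rows by mature arm.

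The deposited values could be turned back into reads. Under the closed form of the parametric variance-stabilizing transformation, with the lowest value of each table as 0 reads and the lowest step above it as 1 read, 1764 of 1764 values in the HEK293 table and 964 of 964 in the ERC table gave whole reads within 0.001. This form was found from the values, after they were seen. The recovered reads gave library totals of 35166 to 42788 in ERC cells and 19512 to 30497 in HEK293 cells, size factors, normalized reads and shares with exact Clopper-Pearson 95% intervals. The limit for a count of 0 was set at 3 counts. The scale is compressed at low counts, so that a log2 difference between rows with few reads understates the ratio of reads.

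All tests used the deposited values within 1 table and compared 2 ultramiR with 2 mir30 libraries, two-sided, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) and Benjamini-Hochberg adjustment over the tested rows. Rows at 0 reads in all 4 libraries (34 of 241 in ERC and 33 of 441 in HEK293) were not tested, which left 207 and 408 rows. The prior degrees of freedom were 8.65 in ERC and infinite in HEK293, where the spread of each row was taken from the trend. The shRNA share was the shRNA's part of the sum of 2 to the power of the deposited value over all rows, with an exact permutation test on its log2, whose smallest two-sided p is 0.333. The rank was the percent of endogenous rows with a smaller signed change, so that every fall counted as smaller than a rise. Lists of microRNAs were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, where at least 3 members were tested. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.

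The design, the lists, the alternatives and the rule for named rows were fixed before the data were examined. The rule named each shRNA row, the 5 endogenous rows with the highest mean, each tested miR-30 family row, up to 10 rows per direction past an adjusted p of 0.05 with both ultramiR libraries on one side of both mir30 libraries, the 5 smallest unadjusted p per direction where fewer than 5 passed, and 2 to 4 members per list with the highest mean. The lists were the miR-30 family, the let-7 and miR-98 family, the miR-17-92 and paralogous clusters, the miR-15/16 family, HOX-cluster, p53-responsive, non-canonical, mesenchymal or fibroblast, blood cell, muscle, neural, epithelial, pluripotency and liver microRNAs, and minor arms marked with an asterisk, of which the tables had 0 rows. Lists matched stems exactly, so gga-mir-222a was in none of them.

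Replicates of a group were compared before they were averaged. No pair held identical values, and a chi-square test of the recovered reads over rows with at least 10 reads in the pair gave 2.76 and 3.73 times its degrees of freedom in ERC and 6.27 and 4.11 in HEK293. The pairs thus differed by more than read counting, as separate cultures or separate library preparations of 1 culture both would. Each library was counted as its own sample because the labels give it as a replicate, and no source says whether the replicates were grown apart.

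The fitting step was tested on 20 simulated tables per cell line, drawn from the means, library sizes and spread of the real libraries. All rows of a comparison were given the same spread. In each simulation 40 rows were changed, drawn only from rows with a mean of at least 10 normalized reads. Among tested endogenous rows, 82 of 206 in ERC and 104 of 407 in HEK293 had a mean of 10 reads or more. The rates of calling a change therefore do not cover rows with fewer reads. For the ERC comparison (207 rows) the fitting step called 57.2% of rows changed 2-fold and 92% of those changed 4-fold, and 4.48% of its calls were unchanged rows. For the HEK293 comparison (408 rows) it called 15.5% and 68.8%, with 0.882% of calls unchanged. In tables with no change it made a call in 0 of 20 for each cell line.

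Alternatives were the replicate letter as a block, median centring, quantile normalization, division by the linearised total, rows with a mean above the table's median, no filter, eBayes without a trend or robust, an adjusted p of 0.1, other denominators of the share, 1 row per microRNA in the lists, and each library left out in turn. Added after the data were seen were voom on the recovered reads, log2 of normalized reads or of reads per library total plus 0.5, rows with a mean of 10 reads or more, crossed letters as pairs, list rows with identical reads counted once, and shares of recovered reads. Pseudocounts for linear values did not apply to log2 values. Genome positions came from GENCODE release 29 (GRCh38), a different build from the authors' hg19, and no chicken position is given because the annotation at hand was of another build than galGal4.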

Results

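Small RNA was sequenced from 8 libraries of cells that carried a short hairpin RNA (shRNA) inside a microRNA backbone. Such a hairpin is cut out of its transcript by the enzymes that process microRNAs, Drosha and then Dicer, and the resulting small RNA is counted beside the cell's own microRNAs. The mir30 cassette carries an added EcoRI restriction site, and the ultramiR cassette is a version in which that site was taken out. The comparison addressed whether the same shRNA gave more small RNA, relative to the microRNA population, from ultramiR than from mir30. One hairpin, shRPA3, was placed in ERC, a chicken cell line. The other, shRenilla, directed at Renilla luciferase, was placed in HEK293, a human embryonic kidney line that the series text names as HEK293T. Each hairpin and cassette was represented by 2 replicate libraries, which gives 4 groups. Because each hairpin was used in 1 cell line and each cell line has its own separately normalized table, the 2 effects are set side by side and no test was made between them.

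The ERC table held 240 endogenous chicken microRNA rows and the shRPA3 row, and the HEK293 table held 440 human microRNA rows and the shRenilla row. Reads in these rows numbered 35418 and 35166 in the mir30 libraries of ERC cells and 39490 and 42788 in the ultramiR libraries. In HEK293 cells they numbered 26885 and 26632 with mir30 and 30497 and 19512 with ultramiR. These totals cover only the listed rows, not all sequenced reads. A count of 0 reads allowed a share of up to 0.00853% in the shallowest ERC library and up to 0.0154% in the shallowest HEK293 library. Intervals and such limits cover counting error only. No source says whether the replicates came from separate infections grown apart, so the p-values measure the spread between these libraries, which may be technical.

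In GENCODE release 29 (GRCh38), MIR30A, whose hairpin is the parent of both cassettes, lies on the minus strand of chromosome 6 at 71403551 to 71403621, in an intron of the long non-coding RNA gene LINC00472. RPA3, which encodes the smallest subunit of the single-strand DNA binding protein RPA, is a protein-coding gene on the minus strand of chromosome 7 at 7636518 to 7718607. The series text gives human RPA3 as the target of shRPA3, while its row in the chicken table is named ggallusrpa3. The hairpins were delivered on a vector and have no position in either genome.

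shRPA3 small RNA rose when the hairpin was moved from mir30 to ultramiR in ERC cells. It made up 1.21% ± 0.311 (SD, n = 2) of the reads in the mir30 libraries and 3.46% ± 0.318 (SD, n = 2) in the ultramiR libraries. With numbered loci counted once, the shRPA3 shares were 1.29% ± 0.337 (SD, n = 2) and 3.71% ± 0.348 (SD, n = 2). The mean normalized read count went from 449.6 ± 132.4 (SD, n = 2) to 1276 ± 153.5 (SD, n = 2), a ratio of 2.84. Relative to the reads of the miR-30 family, shRPA3 stood at 12.8% ± 1.59 (SD, n = 2) with mir30 and at 38.3% ± 3.20 (SD, n = 2) with ultramiR.

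The single libraries behind these means held 349 and 501 shRPA3 reads with mir30 and 1278 and 1577 with ultramiR. The corresponding shares were 0.985% (exact Clopper-Pearson 95% interval 0.885% to 1.09%) and 1.42% (1.30% to 1.55%), against 3.24% (3.06% to 3.42%) and 3.69% (3.51% to 3.87%). On the deposited log2 scale the difference was 1.47 (95% interval 1.08 to 1.86), with a limma adjusted p of 0.00119 over 207 rows, and both ultramiR libraries lay above both mir30 libraries. As a share of the summed linearised values, shRPA3 went from 1.13% ± 0.276 (SD, n = 2) to 3.11% ± 0.286 (SD, n = 2). The two-sided exact permutation test of that share gave p = 0.333, the smallest value that 2 against 2 libraries allow. The limma call ended with quantile normalization (adjusted p = 0.0541), with rows at 0 reads included (adjusted p = 0.477), with reads scaled to the library total (adjusted p = 0.0880) and when any single library was left out (adjusted p 0.180 to 0.558), while the log2 difference stayed between 1.18 and 1.75 in these settings.

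**Figure D1:**
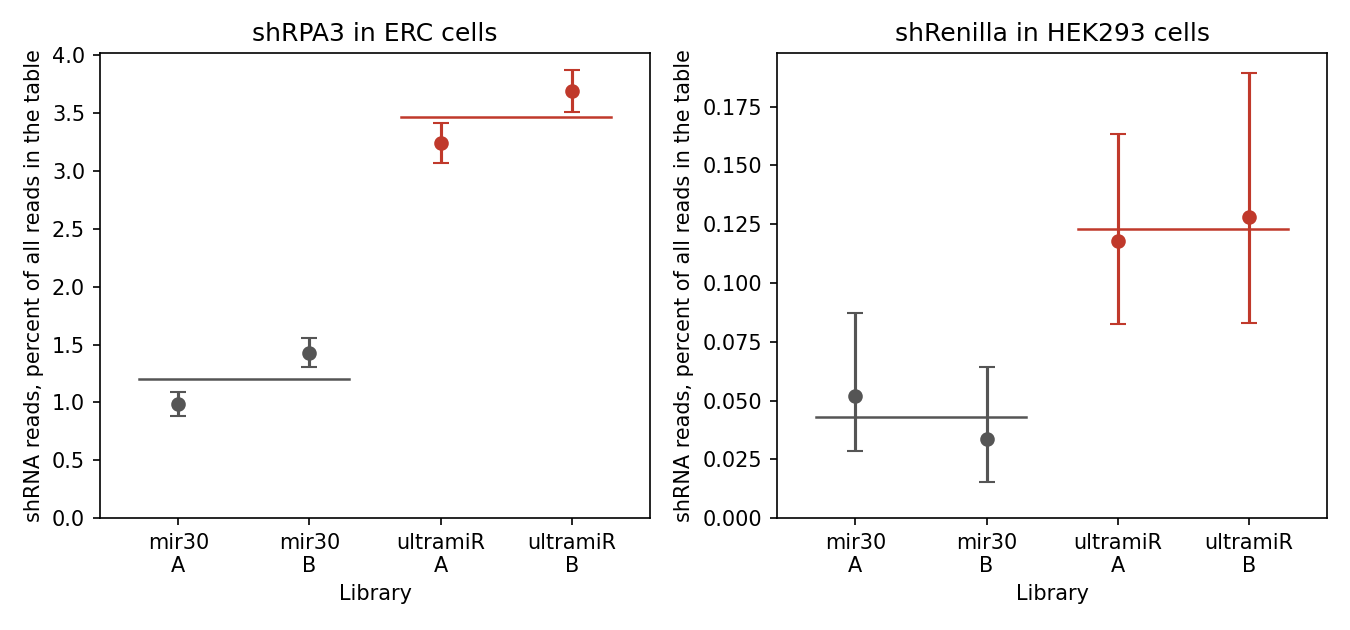
Reads of the shRNA as a percent of all reads in the table for each of the 8 libraries, with shRPA3 in ERC cells on the left and shRenilla in HEK293 cells on the right, each panel with its own vertical scale. Points are single libraries with exact 95% binomial intervals, horizontal lines are group means, and in both panels the 2 ultramiR libraries lie above the 2 mir30 libraries (1.21% against 3.46% and 0.0429% against 0.123% on average).

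No endogenous chicken microRNA passed the test between the same libraries. Of 206 tested rows, 0 had a limma adjusted p under 0.05, 13 had an unadjusted p under 0.05, and voom on the recovered reads called 1 row, gga-mir-222a. The rise in shRPA3 was larger than that of any of the 206 endogenous rows on the deposited scale, including the 11 rows within 1 log2 unit of its mean. With voom, which does not compress low counts, 8 of the 206 rows had a larger rise. Endogenous changes ran from -0.34 at the 5th percentile to 0.36 at the 95th percentile on the deposited log2 scale and from -1.0 to 1.5 with voom, where shRPA3 stood at 1.54. Both 95th percentiles equal the values of the gga-mir-133 rows, which held the same few reads. Among the 82 endogenous rows with a mean of 10 reads or more, the largest rise was 0.41 on the deposited scale. In 21 rows both ultramiR libraries lay above both mir30 libraries and in 26 they lay below, together 22.8% of rows, where all splits of the 4 libraries into pairs gave 24.3% on average, ties included.

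The 5 most abundant chicken microRNAs were gga-mir-22, gga-mir-21, gga-mir-92, gga-mir-31 and gga-mir-30a. gga-mir-22 took 21.2% of the reads on average and differed by 0.00 on the log2 scale (95% interval -0.13 to 0.13). gga-mir-21, a microRNA abundant in many proliferating cells, took 15.5% and differed by 0.08 (-0.10 to 0.25). gga-mir-92, of the miR-17-92 cluster, took 15.3% and differed by -0.21 (-0.36 to -0.05), and gga-mir-31 took 5.27% and differed by -0.23 (-0.44 to -0.03). Neither passed after adjustment (limma adjusted p = 0.612 for both).

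Among the rows with the smallest unadjusted p, none of which passed, gga-mir-222a was lower in ultramiR by a log2 difference of -0.48 (95% interval -0.73 to -0.23, limma adjusted p = 0.150). Its reads numbered 1141 and 1216 with mir30 and 963 and 996 with ultramiR, and voom gave it an adjusted p of 0.00277. The other rows on the lower side, besides gga-mir-92 and gga-mir-31, were gga-mir-365-1 at -0.46 and gga-mir-6553 at -0.36, each with at most 6 reads in a library. On the higher side, gga-mir-33, a regulator of cholesterol export, differed by 0.52 (0.17 to 0.87) with 5 and 3 reads against 12 and 16. gga-mir-153 differed by 0.45, gga-mir-3536 by 0.47, and gga-mir-135a-3 and gga-mir-1451 by 0.42 each. These 4 rows had at most 7 reads in any library.

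The chicken miR-30 family, the natural relatives of the cassettes, had 5 tested rows, of which 1 was higher, 4 were lower and 0 passed, with 0 to 2 higher under other scalings. gga-mir-30a differed by -0.03 (95% interval -0.32 to 0.27), gga-mir-30d by less than 0.01 in size and gga-mir-30e by less than 0.01 in size. gga-mir-30c-1 and gga-mir-30c-2 differed by -0.35 and -0.36, and their read counts were within 3 of each other in every library, so they count as 1 measurement. Both had an unadjusted limma p under 0.05, and both are part of the miR-30 family reads to which shRPA3 was compared. The family as a list was not called (camera adjusted p = 0.170).

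Of the 8 chicken lists with at least 3 tested members, 2 were called higher by camera with a preset correlation, both on few reads. The HOX-cluster list, microRNAs encoded among the HOX genes, had 5 of 7 members higher and a median log2 difference of 0.31, with gga-mir-196-1 at 0.31, gga-mir-196-3 at 0.30, gga-mir-196-4 at 0.40 and gga-mir-10b at -0.09. Its camera adjusted p was 0.0113, and the adjusted p was 0.680 with an estimated correlation. That estimate was -0.148, below the preset 0.01, so a higher correlation among the members was not what ended the call. The muscle list had 4 of 4 members higher at a median of 0.36, with an adjusted p of 0.0113 that became 0.680 with an estimated correlation. Its members, gga-mir-133a-1, gga-mir-133a-2, gga-mir-133b and gga-mir-133c, held the same reads, 0 and 1 with mir30 and 1 and 5 with ultramiR. The 5 higher members of the HOX-cluster list were all loci of miR-196. With 1 row per microRNA that list had 3 members, 1 higher and 2 lower. Its mean log2 difference was then 0.07, down from 0.24, and it was not called (camera adjusted p = 0.535). The muscle list kept 3 members with the same reads and a mean of 0.36 and was not called either (adjusted p = 0.0783).

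The other chicken lists were not called. In the let-7 and miR-98 family 9 of 11 rows were higher (camera adjusted p = 0.451), with gga-let-7j at 0.16 and gga-let-7a-2 at 0.15. In the miR-17-92 and paralogous clusters 8 of 9 were lower (adjusted p = 0.294), though 4 were higher and 4 lower after quantile normalization, with gga-mir-17 at -0.01 and gga-mir-20a at -0.09. In the miR-15/16 family 4 of 6 were higher (adjusted p = 0.526), with gga-mir-15c at 0.11 and gga-mir-15b at 0.08. The mesenchymal or fibroblast list had 4 of 5 higher (adjusted p = 0.451), or 2 of 5 after quantile normalization, with gga-mir-199-1 at 0.22 and gga-mir-221 at -0.29. The neural list had 4 of 6 lower (adjusted p = 0.642), or 2 higher and 2 lower after quantile normalization and 5 of 6 lower after median centring, with gga-mir-138-1 at 0.02 and gga-mir-128-1 at -0.28. The blood cell (gga-mir-223), epithelial (gga-mir-429) and p53-responsive (gga-mir-215) lists had 1 tested row each, at 0.24, -0.13 and 0.19, and the non-canonical, pluripotency and liver lists had none. Adjusted over the list alone, 0 members passed in any list.

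shRenilla small RNA was also more abundant with ultramiR in HEK293 cells, at far fewer reads. It made up 0.0429% ± 0.0129 (SD, n = 2) of the reads with mir30 and 0.123% ± 0.00713 (SD, n = 2) with ultramiR. The mean normalized read count was 10.2 ± 2.61 (SD, n = 2) against 27.5 ± 0.962 (SD, n = 2), a ratio of 2.70. Relative to the reads of the miR-30 family, it stood at 1.75% ± 0.365 (SD, n = 2) with mir30 and 5.12% ± 0.244 (SD, n = 2) with ultramiR.

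The libraries held 14 and 9 shRenilla reads with mir30 and 36 and 25 with ultramiR. The shares were 0.0521% (exact 95% interval 0.0285% to 0.0874%) and 0.0338% (0.0155% to 0.0641%), against 0.118% (0.0827% to 0.163%) and 0.128% (0.0829% to 0.189%), so that the interval of 1 mir30 library overlapped those of both ultramiR libraries. On the deposited log2 scale the difference was 0.90 (95% interval 0.32 to 1.48), and both ultramiR libraries lay above both mir30 libraries. It did not pass over the 408 tested rows (limma adjusted p = 0.330). As 1 of the 2 hairpins the comparison is about, it had a limma p adjusted over those 2 rows of 0.00242, an adjustment chosen after the values were seen. With 1 ultramiR library left out, its limma p before any adjustment was 0.0649 or 0.0730, so that call ended too. The deposited scale compresses low counts, and voom on the recovered reads gave a log2 difference of 1.41. As a share of the summed linearised values it went from 0.0767% ± 0.0135 (SD, n = 2) to 0.150% ± 0.00690 (SD, n = 2), with a two-sided exact permutation p of 0.333, again the smallest possible.

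No endogenous human microRNA passed the test. Of 407 tested rows, 0 had a limma adjusted p under 0.05, 22 had an unadjusted p under 0.05, and voom called 0. Of these rows 405 fell or rose less than shRenilla did, and the exceptions were hsa-miR-4532 and hsa-miR-3676-5p. With voom, 18 of the 407 rows had a larger rise. In 45 rows both ultramiR libraries lay above both mir30 libraries and in 45 they lay below, together 22.1%, where all splits of the 4 libraries into pairs gave 23.8% on average. Endogenous changes ran from -0.48 at the 5th percentile to 0.52 at the 95th on the deposited scale and from -1.16 to 1.24 with voom.

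**Figure D2:**
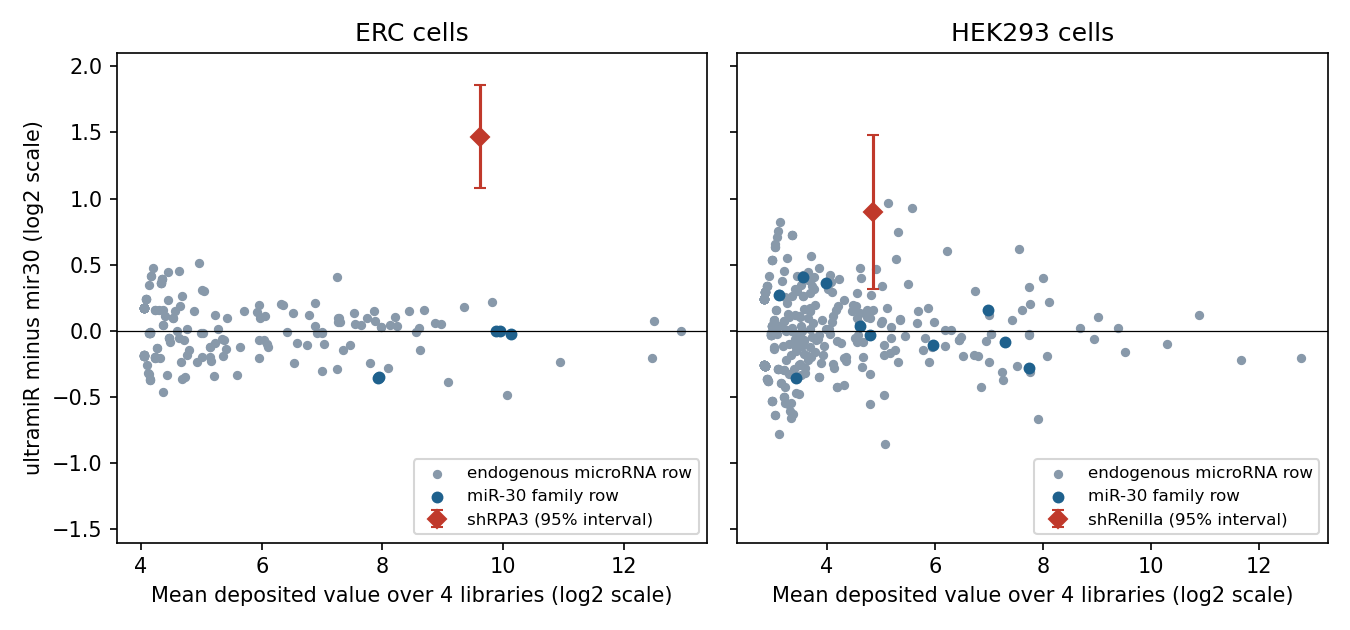
Difference between ultramiR and mir30 libraries on the deposited log2 scale (vertical axis) against the mean deposited value over 4 libraries (horizontal axis) for each tested row, in ERC cells on the left and HEK293 cells on the right. Grey points are endogenous microRNAs, blue points the miR-30 family and the red diamond the shRNA with its 95% interval, at 1.47 for shRPA3, above all 206 endogenous rows, and at 0.90 for shRenilla, below 2 of 407.

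The 5 most abundant human microRNAs were hsa-miR-92a-3p, hsa-miR-191-5p, hsa-miR-10a-5p, hsa-miR-148a-3p and hsa-miR-16-5p. hsa-miR-92a-3p took 30.4% of the reads on average and differed by -0.21 on the log2 scale (95% interval -0.49 to 0.07). It is encoded at MIR92A1 on chromosome 13 (91351314 to 91351391, plus strand, within the cluster transcript MIR17HG) and at MIR92A2 on chromosome X (134169538 to 134169612, minus strand), both in GRCh38. hsa-miR-191-5p, from an intron of DALRD3 on chromosome 3 (49020618 to 49020709, minus strand), took 14.0% and differed by -0.22 (-0.54 to 0.10). hsa-miR-10a-5p, from the HOXB cluster on chromosome 17 (48579838 to 48579947, minus strand), took 8.23% and differed by 0.12 (-0.23 to 0.47). hsa-miR-148a-3p, from chromosome 7 (25949919 to 25949986, minus strand, in no other annotated gene), differed by -0.10, and hsa-miR-16-5p, encoded at MIR16-1 in an intron of DLEU2 and at MIR16-2 in an intron of SMC4, by -0.16.

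The smallest unadjusted p-values on the higher side belonged to hsa-miR-4532 at 0.97 (95% interval 0.39 to 1.54), hsa-miR-3676-5p at 0.93 (0.36 to 1.49), hsa-miR-186-3p at 0.82, hsa-miR-1307-5p at 0.75 and hsa-miR-1246 at 0.62 (0.12 to 1.12), none of which passed. hsa-miR-4532 had 18 and 13 reads with mir30 and 46 and 35 with ultramiR, and hsa-miR-1246 had 151 and 160 against 285 and 202. The 2 libraries of a group could lie far apart, as for hsa-miR-1307-5p, which had 46 and 8 reads with mir30. On the lower side stood hsa-miR-1275 at -0.86 (-1.43 to -0.28), hsa-miR-92b-3p at -0.67, hsa-miR-576-3p at -0.78, hsa-miR-1291 at -0.66 and hsa-miR-3074-3p at -0.63. Limma adjusted p-values of these 10 rows were 0.273 or higher.

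The human miR-30 family had 10 tested rows, with 5 higher, 5 lower and 0 past the threshold (camera adjusted p = 0.951), or 6 higher divided by the linearised total. The 5p arms differed by 0.16 for hsa-miR-30a-5p, -0.03 for hsa-miR-30b-5p, -0.11 for hsa-miR-30c-5p, -0.28 for hsa-miR-30d-5p and -0.09 for hsa-miR-30e-5p. The 3p arms, at 18 reads or fewer per library, differed by 0.36 for hsa-miR-30a-3p, 0.41 for hsa-miR-30c-1-3p, 0.27 for hsa-miR-30c-2-3p, -0.36 for hsa-miR-30d-3p and 0.04 for hsa-miR-30e-3p.

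None of the 10 human lists was called by camera. In the let-7 and miR-98 family 7 of 10 rows were lower (camera adjusted p = 0.395), with hsa-let-7f-5p at -0.43 and hsa-let-7a-5p at -0.12. The miR-15/16 family had 7 of 10 lower (adjusted p = 0.662), with hsa-miR-15b-5p at -0.14, and the p53-responsive list 4 of 5 lower (0.662), with hsa-miR-192-5p at -0.08 and hsa-miR-34a-5p at -0.33. Divided by the linearised total, these lists had 5 of 10 and 2 of 5 lower. The miR-17-92 and paralogous clusters had 8 of 17 higher (0.977), or 12 of 17 divided by the linearised total, with hsa-miR-25-3p at -0.19 and hsa-miR-17-5p at -0.05; its median was below 0 while its mean lay above 0. The HOX-cluster list had 5 of 7 higher (0.951), with hsa-miR-10b-5p at 0.10 and hsa-miR-196b-5p at -0.37. The mesenchymal or fibroblast list had 6 of 6 higher (0.662), or 4 of 6 after quantile normalization and 5 of 6 with voom, with hsa-miR-222-3p at 0.02 and hsa-miR-21-5p at 0.08. The non-canonical list, microRNAs made without Drosha or without Dicer, had 3 of 5 lower (0.951), with hsa-miR-320a at -0.41 and hsa-miR-484 at 0.35. The blood cell list had 2 of 3 higher (0.951), or 1 higher and 1 lower after quantile normalization, with hsa-miR-486-5p at -0.31, and its median lay above 0 while its mean and camera pointed down.

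The neural list had 4 of 4 rows lower, at a median log2 difference of -0.25, with hsa-miR-128 at -0.11 and hsa-miR-9-5p at -0.12. By fry, which asks only whether the members move one way on balance, its adjusted p was 0.00966, while camera gave 0.395 and the adjusted p was 0.968 with an estimated correlation. Its other members, hsa-miR-138-5p and hsa-miR-219-1-3p, had 2 reads or fewer in each library. The muscle, epithelial, pluripotency and liver lists had no tested rows. Adjusted over the list alone, 0 members passed in any list.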

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

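Groups of 2 libraries are too small for a search for single libraries far from the others. Of 27 named microRNAs present in both tables, with arms and loci summed, 1 had both ultramiR libraries on one side of both mir30 libraries in each cell line and in opposite directions. Others had mean ratios on opposite sides of 1 with overlapping libraries. Of all tested endogenous rows, 22.8% in ERC and 22.1% in HEK293 were separated in either direction. A single opposite case among 27 may therefore arise by chance. The ratio of mean normalized miR-31 reads, ultramiR over mir30, was 0.848 in ERC cells, where both ultramiR libraries lay below both mir30 libraries, and 1.58 in HEK293 cells, where both lay above. The chicken row gga-mir-31 held 2049 and 1960 reads with mir30 and 1985 and 2004 with ultramiR, and the human row hsa-miR-31-5p held 17 and 15 against 30 and 22. The chicken reads overlapped before scaling and were separated only as normalized reads, at 2090 and 2125 with mir30 against 1813 and 1759 with ultramiR. The difference between the cell lines was not tested, since the tables were normalized separately and the hairpins differ.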

How the results depend on the processing

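The voom, read-based, crossed-letter, 10-read and identical-reads settings were chosen after the data were seen. The shRNAs were higher in ultramiR under every setting run. For shRPA3 the call ended at log2 differences of 1.46 with quantile normalization (adjusted p = 0.0541), 1.47 with no filter (0.477) and 1.54 with reads per library total (0.0880), and with 1 library left out, at 1.18 to 1.75 (0.180 to 0.558), where the lone library is assumed to vary like the other pair. The last of these fits had fewer libraries, but what ended the call in any of these settings was not tested. Adjusted over all tested rows, shRenilla stayed short of the threshold throughout, at log2 differences of 0.761 to 1.04 with 1 library left out and 1.41 with voom. The log2 share ratio with 1 library left out was 1.23 to 1.73 for shRPA3 and 0.801 to 1.16 for shRenilla. The rank of shRPA3 moved from 100% to 96.1% with voom and that of shRenilla from 99.5% to 95.6%, and the cause was not tested. Among rows near its mean shRenilla ranked at 97.5%. There 2 of 81 rows lay at or above it, against 2 of 407 over all rows, so this lower percent comes from comparing fewer rows.

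Endogenous calls in ERC cells went from 0 to 2 with quantile normalization, 1 with the linearised total, 1 among rows with a mean above the table's median, 3 with no filter, 1 with voom and 1 with rows of 10 reads or more. With 1 library left out they were 0 to 30 in ERC (30 without ultramiR replicate A and 23 without B, of which 24 and 18 were rows whose remaining pair had equal values) and 22 to 48 in HEK293, where all calls (45, 32, 22 and 48) were such rows. List calls in ERC went from 2 to 0 with an estimated correlation, from 2 to 0 with 1 row per microRNA and from 2 to 0 with rows of identical reads counted once; these last settings test fewer rows.

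With the replicate letter as a block, the log2 difference was 1.47 for shRPA3 and 0.90 for shRenilla, with 0 endogenous calls in each table, 2 list calls in ERC and 0 in HEK293, so it changed no limma or camera call. By fry the HEK293 neural list went from an adjusted p of 0.00966 to 0.149. No source says whether libraries with the same letter belong together. Their deviations correlated across microRNAs, which are not independent, at r = 0.128 over 82 ERC rows and -0.344 over 104 HEK293 rows with a mean of 10 reads or more. Over all endogenous rows r was 0.065 (240 ERC rows) and -0.069 (440 HEK293 rows). These values do not settle whether the letters are pairs. With letters crossed, endogenous calls numbered 3 in HEK293, where the correlation was negative, and 2 in ERC, where it was not.

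Of 1696 alternative values of 103 named endogenous rows, 1671 kept their side of the threshold and 25 passed it, 14 of them with 1 library left out. The sign was opposite in 116, of which 83 had 1 library left out and 0 passed. What kept shRenilla, at 9 to 36 reads per library, short of the threshold was not tested.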

Other observations

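The tests of the size factors, uninfected cells, identical reads, miR-221 and other non-coding RNA sequence in this part were chosen after the results they bear on had been seen. In both cell lines the miR-92 member of the miR-17-92 cluster far outnumbered its neighbours. gga-mir-92 had 23315 reads over the 4 ERC libraries against 378 for gga-mir-17 and 66 for gga-mir-18a, and hsa-miR-92a-3p had 31739 reads over the 4 HEK293 libraries against 352 for hsa-miR-17-5p and 73 for hsa-miR-18a-5p. The human microRNA is also made from a second locus on the X chromosome, so its reads do not come from this cluster alone. hsa-miR-486-5p, a microRNA abundant in red blood cells, had 242, 273, 277 and 143 reads in the HEK293 libraries.

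Both hairpins had a higher share of reads in the ultramiR libraries, for shRenilla without passing over all tested rows, and 2 technical explanations were examined. Were the authors' size factors the cause, other denominators would remove the difference, but over 4 denominators of recovered reads the lowest log2 ratio was 1.48 for shRPA3 and 1.46 for shRenilla. Unscaled reads already differed, at 349 and 501 against 1278 and 1577 for shRPA3 and 14 and 9 against 36 and 25 for shRenilla. Library totals varied less than that, and the denominators overlap. They could thus hardly have removed the difference and add little to the unscaled reads. For shRenilla, all rows and numbered loci counted once gave the same shares, so they count as 1 denominator. Uninfected cells in the mir30 cultures could account for at most a ratio of 1.11 if over 90% of cells carried the hairpin, as the series text states, and the lower 95% bounds of the ratio on the deposited scale were 2.11 for shRPA3 and 1.25 for shRenilla. Over all settings that kept the 4 libraries, these bounds fell no lower than 1.47 and 1.19. With 1 ultramiR library left out they were 0.616 and 0.526 for shRPA3 and 0.892 and 0.846 for shRenilla. Bounds above 1.11 thus rest on having both ultramiR libraries. They measure the spread between these libraries, which may be technical, so they do not exclude uninfected cells. For shRenilla they also rest on 9 to 36 reads per library, and its change did not pass over all tested rows (limma adjusted p = 0.330). Differences in transcription, insertion site or copy number between the cultures stay open, since no table measures the hairpin's transcript. A difference in processing between the cassettes, which the design names, remains a hypothesis and was not tested apart from these.

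The HOX-cluster and muscle lists of ERC cells may owe their calls to the same reads being counted in several rows. Of 21 chicken names with several numbered loci and reads, 8 had a pair of loci with identical reads in all 4 libraries and 15 a pair within 3 reads. With rows of identical reads counted once, the HOX-cluster list kept 5 members and its mean log2 difference went from 0.24 to 0.18, with an adjusted p of 0.223 and an unadjusted camera p of 0.0458, so its call ended with a smaller mean and fewer rows. The muscle list kept 1 member, at 0.36, too few for a list test. The 4 muscle rows held the same reads, so that call counted 1 measurement 4 times. Whether the muscle microRNAs rose cannot be told at these few reads. In the HOX-cluster list the members that rose were all loci of miR-196. With 1 row per microRNA, 1 member was higher and 2 were lower, at a median of -0.01. The list thus showed no rise beyond that 1 microRNA. Whether miR-196 itself rose cannot be told, since none of its rows passed. No biological explanation was tested.

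gga-mir-222a was lower in ultramiR libraries of ERC cells, and a lower level of the transcript it shares with miR-221 could be the source. gga-mir-221 differed by -0.29 on the log2 scale (95% interval -0.70 to 0.13), an interval that holds both 0 and the -0.48 of gga-mir-222a, so a shared change and a change in gga-mir-222a alone cannot be told apart at 505 reads of gga-mir-221 over the 4 libraries.

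Among the largest rises in HEK293 cells, hsa-miR-4532, hsa-miR-3676-5p and hsa-miR-1246 match ribosomal, transfer and small nuclear RNA sequence, and more fragments of such RNAs in the ultramiR libraries could be a candidate source. The list of such rows was drawn up from general knowledge after the values were seen and was revised once before it was tested. In the revised list of 15, the 12 rows other than these 3 had 7 higher and 5 lower, with a camera p of 0.400 (0.491 with an estimated correlation). In the first list of 11, the other 8 had 3 higher and 5 lower, with a camera p of 0.794. Neither version gave support, and with members going both ways and few reads the question stays open.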
